A study of Mus musculus with 10 samples.

How the data were processed

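Gene expression was measured by RNA sequencing in 10 libraries from whole mouse brains at embryonic day 18.5 after removal of the olfactory bulbs. The labels give 5 genotypes with 2 libraries each: a control heterozygous for COP1 (control), a COP1 knockout (KO), a knockout of COP1 and cJun (DKO), of COP1, cJun and ETV1 (TKO), and of all of these plus ETV5 (QKO). Libraries are named by genotype and a number given in accession order, which pairs nothing. Per the labels' protocols, polyadenylated RNA libraries were made from 1 microgram of total RNA with a TruSeq kit, pooled 5 to a lane, and read as 75 bp paired ends. The labels do not say which libraries shared a lane, so no batch could be tested. They give neither litter nor sex, and nothing states that the 2 libraries of a group came from separate litters. The p-values therefore measure the spread between these samples, which may be technical in KO, TKO and QKO. In control and in DKO the libraries differ in their sex pattern (Results), so they came from different embryos.

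Reads were aligned with GSNAP to mouse build NCBIM37, per the submitters' processing notes, which give no version. Each deposited count is the number of reads that aligned uniquely to a gene model, per the file headers. The second deposited value is an RPKM adjusted by a size factor for each library (nRPKM), per the file headers. Count divided by nRPKM differed between any pair of libraries by 1 factor for every gene, to a relative deviation of 4e-14, and that factor equalled the ratio of their median-of-ratios size factors. The gene annotation release, the handling of strand and the treatment of reads shared between gene copies are not given in the sources used here. A gene and its antisense partner, or a gene and a near-identical copy, may therefore share reads.

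The files list 28059 Entrez gene identifiers and no symbols. Symbols came from RefSeq for assembly GRCm38.p6, used only for names and for which genes neighbour each other or share a chromosome. It named 24998 identifiers (89.1%), which held 95.8% of the counts. Another 3061 identifiers stayed unnamed, were tested, and are written as ID followed by the number. Hbb-b1 and Hbb-b2 have the same count in every library and are 1 measurement under 2 identifiers. No coordinates are printed, because no annotation of the authors' build was used here.

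Library totals ranged from 31996944 to 54594523 counts, so that a floor of 3 counts corresponded to between 0.055 and 0.0938 CPM (counts scaled to a common library total), a bound on counting error only. To look for a library deposited more than once, the libraries of each group were compared by a chi-square test over genes with at least 20 counts. The statistic per degree of freedom was between 7.51 and 19.5, so no group held 2 libraries with counts as close as those of 1 library. The test says nothing else about the spread within a group.

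The comparisons and their tests were fixed before the data were examined, as were the gene lists, the rule for naming genes and the alternatives, apart from those stated as added later. Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test on a model of 5 group means over all 10 libraries, TMM normalization and Benjamini-Hochberg adjustment over all genes tested. Genes were kept by filterByExpr, which left 18671 and set aside 9388. A gene was called at an adjusted p under 0.05. The shared fit had 5 residual degrees of freedom and a common biological coefficient of variation of 0.0821. Errors of log2 fold changes are standard errors derived from the quasi-likelihood F statistic. Levels are mean nRPKM ± SD.

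The 8 comparisons were 5 main ones (KO vs control, DKO vs KO, TKO vs DKO, QKO vs TKO, QKO vs control) and 3 others (DKO vs control, TKO vs control, QKO vs KO). The 37 gene lists covered cell types, brain regions, tissues that may adhere to a brain, and signalling or stress pathways. They were tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists. Targeted and sex-linked genes were left out of the lists. A gene can be on more than 1 list: Gfap is an astrocyte and a reactive glia gene, and Vim, Nes and Tnc are reactive glia and radial glia genes. The results of these lists are therefore not independent. Of the list symbols, 2 matched no identifier. The erythroid list holds Hbb-b1 and Hbb-b2 as 2 genes although they are 1 measurement. Its tallies, its camera p and the counts of calls therefore enter that measurement 2 times. With a correlation estimated from these libraries, camera called 0 lists in each of the 8 comparisons, and between 1 and 6 lists had an unadjusted p under 0.05. fry, which asks whether the genes of a list move one way on balance, called between 0 and 4 lists.

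Genes are named by a fixed rule. The targeted genes and Etv4 are always given. In each main comparison up to 10 genes each way are named (5 in the others), those with the largest fold among called genes with at least 1 CPM in the higher group and no overlap between libraries, leaving out clone names, pseudogenes and sex-linked genes. Up to 4 members with the lowest p may be named from each list that passed camera or had at least 3 called members, and the text names part of these. A set of 12 cell type markers is named whatever its p: Vim, Gfap, Olig1, Olig2, Sox10, Pdgfra, Mki67, Eomes, Tbr1, Gad1, Rbfox3 and 1 that is not reported here.

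The share of the KO change kept in DKO, TKO and QKO was measured with separate libraries for choosing and measuring it. The 500 genes with the largest difference between 1 KO and 1 control library were weighted by that difference, among genes with a mean log2 CPM of at least 2, and the share was computed against the other KO and control libraries. It was averaged over the 4 ways to choose. Overlaps of calls were set beside 20 simulations of unchanged groups. All libraries were redrawn gene by gene from the fitted means and dispersions, and the simulated control or KO libraries were shared between comparisons. Differences between libraries of a group that many genes share were therefore not simulated.

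The scripts were tested on simulated counts drawn from the means, dispersions and totals of the real libraries. For KO vs control, with 200 changed genes and 18550 genes tested, edgeR called 46.3% of those changed 1.5-fold, 83.6% at 2-fold and 90.9% at 4-fold, with 6 false calls among 153. With no gene changed it made 0 calls. Simulated shares of 0, 50 and 100% came back as 8.6, 53.6 and 97.6%.

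Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of 1 CPM in 2 of the 4 libraries compared, a fit of the 2 groups alone, a covariate for Xist, and leaving out each library. Where that left a group with 1 library, it was assumed to vary like the others. The share was recomputed with 200 and 1000 genes and with a mean log2 CPM of at least 0 and 4. Added after the data were seen were a fit without the 2 libraries with high Xist, a covariate for the HOX genes, and the share over genes of 4 glial lists.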

Results

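Messenger RNA was counted in 10 libraries from embryonic brains, 2 for each of 5 genotypes. The controls held 43384681 and 43915724 counts, KO 54594523 and 40019481, DKO 46656815 and 31996944, TKO 41113475 and 33403801, and QKO 38052935 and 41782062. The 10 most abundant genes took between 2.61 and 2.78% of the counts of a library. In control 1 and DKO 1, Xist, the RNA of the inactive X chromosome, stood at 1840 and 1464 CPM, and the Y-linked Uty had 0 counts. In the other 8 libraries Xist was between 0.924 and 1.94 CPM and Uty was between 22.95 and 27.1 CPM. These are the patterns of female and of male tissue. Control and DKO each held 1 library of either pattern, and KO, TKO and QKO held the male pattern only. Sex is therefore unbalanced in each comparison of KO, TKO or QKO with control or DKO. It is balanced in DKO vs control and in comparisons among KO, TKO and QKO. In those, calls lost in a fit that adjusts for Xist or drops the libraries with high Xist do not show a sex imbalance.

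COP1 is a ubiquitin ligase adaptor whose known substrates include cJun and the ETS factors ETV1, ETV4 and ETV5. By the labels, the series removed cJun, ETV1 and ETV5 one after another from brains without COP1. Among the targeted genes, Jun (gene 16476) followed the labels: it stood at 14.99 ± 0.00540 nRPKM (SD, n = 2) in controls and 15.7 ± 0.565 in KO, and at 2.27 ± 0.940 in DKO, 1.54 ± 0.0818 in TKO and 1.75 ± 0.425 in QKO. Cop1 (gene 26374) was 4.87 ± 0.184 in controls and 3.998 ± 0.228 in KO, a log2 fold change of -0.28 ± 0.09 that did not pass (adjusted p = 0.27). Etv1 (gene 14009) was at 2.04 ± 0.0896 nRPKM in DKO, and higher, at 3.74 ± 0.0893, in the libraries labelled TKO. Etv5 (gene 104156) was at 3.84 ± 0.128 in the libraries labelled TKO and 4.04 ± 0.0927 in those labelled QKO. Counts over a whole gene cannot show the loss of an exon, so the counts of Cop1, Etv1 and Etv5 do not check the labels. Jun separates only control and KO from DKO, TKO and QKO. All directions below rest on the labels, that of KO vs control included.

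**Figure D1:**
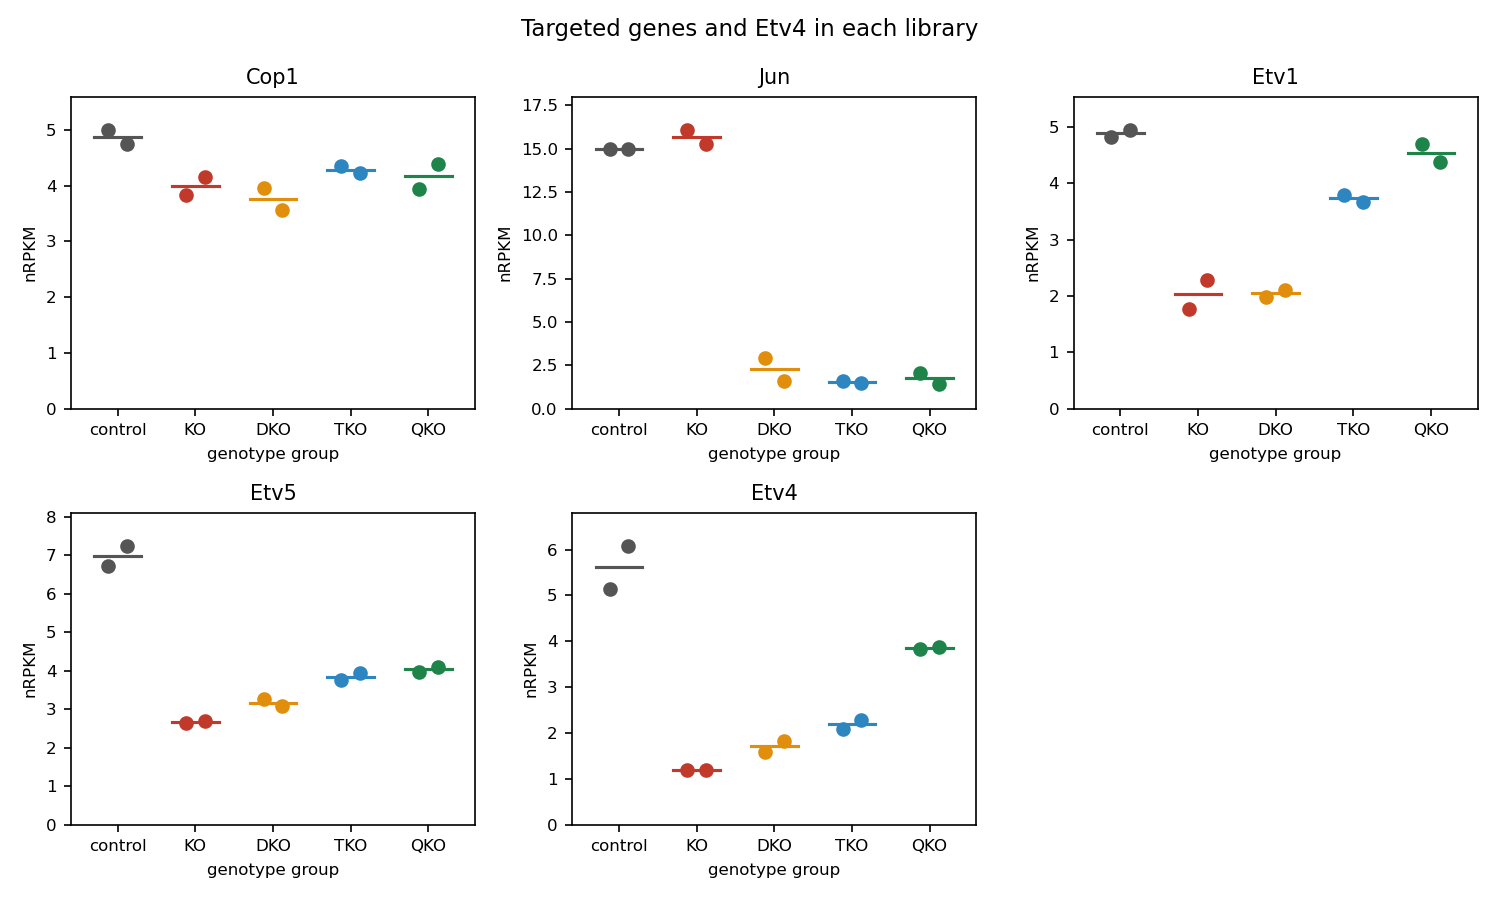
Normalised expression (nRPKM, linear axis from 0) of Cop1, Jun, Etv1, Etv5 and Etv4 in the 10 libraries, by genotype. Points are libraries and lines are means of 2; Jun lies between 1.44 and 2.94 in the DKO, TKO and QKO libraries and between 14.988 and 16.1 in the others, while Etv4 is at 1.18 and 1.20 in KO.

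KO vs control asked what the loss of COP1 changes in the brain. Some transcripts of oligodendrocyte precursor cells (OPCs), astrocytes and radial glia rose in KO. Olig2, a transcription factor of OPCs, rose 2.15-fold (log2 1.11 ± 0.09 SE, n = 2 per group, edgeR adjusted p = 0.000224), and its neighbour Olig1 rose 2.32-fold (1.21 ± 0.13). Gfap, an intermediate filament of astrocytes, rose 3.98-fold (1.99 ± 0.26) and Vim, a filament of radial glia, 1.58-fold (0.66 ± 0.07). The transcripts of the ETS factors fell, Etv4 4.67-fold (-2.22 ± 0.12), Etv5 2.60-fold (-1.38 ± 0.08) and Etv1 2.41-fold (-1.27 ± 0.11), while Jun did not pass (0.07 ± 0.19). HOX genes, which mark the caudal hindbrain, were also lower, with Hoxa4 at -4.95 ± 0.94 and Hoxb2 at -2.68 ± 0.44.

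In all, 137 genes changed, 94 higher and 43 lower (139 and 104 by DESeq2). Of the 15 OPC genes measured, 6 rose and 9 did not pass (9 rose adjusted over the list alone), with a median log2 fold change of 0.40. Sox10, a regulator of oligodendrocyte fate, rose by 1.02 ± 0.16, Pdgfra, the OPC growth factor receptor, by 0.58 ± 0.08 and Sox8 by 0.64 ± 0.08. Camera's adjusted p for the list was 1.71e-13, and adjusted p = 0.162 with an estimated correlation. Of 18 astrocyte genes 4 rose (5 higher and 2 lower adjusted over the list alone), among them Fgfr3 (0.78 ± 0.10), Aldh1l1 (0.60 ± 0.08) and Slc1a3 (0.37 ± 0.07). That list passed camera at 0.00894, with adjusted p = 0.541 with an estimated correlation. Of 13 reactive glia genes 3 rose, Gfap, Vim and Nes (0.56 ± 0.08), and 4 rose and 1 fell adjusted over the list alone. Gfap is also counted in the astrocyte list, and Vim and Nes in the radial glia list. Of 19 radial glia genes 3 rose, including Egfr (0.69 ± 0.09), and Pdpn fell (-0.51 ± 0.09). Adjusted over the list alone, 8 radial glia genes rose and 2 fell. These lists had camera adjusted p of 0.000262 and 0.000823, and adjusted p = 0.162 with an estimated correlation for both. Trib1, a pseudokinase that binds COP1, rose by 0.91 ± 0.08, and its list of 8 COP1 ligase genes passed camera at 0.0399 with 1 member called, 2 adjusted over the list alone, and adjusted p = 0.48 with an estimated correlation.

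Of 12 intermediate progenitor genes 2 fell (5 adjusted over the list alone), Eomes, the factor of cortical intermediate progenitors (-0.76 ± 0.15), and Neurod1 (-0.33 ± 0.07), with a camera adjusted p of 0.000823 and adjusted p = 0.338 with an estimated correlation. Of 20 neuronal maturation genes Nefh, a neurofilament of large axons, fell (-0.90 ± 0.13), while 1 rose and 6 fell adjusted over the list alone. Camera gave that list 0.0013, and adjusted p = 0.217 with an estimated correlation. The striatal peptide genes Tac1 (-0.52 ± 0.09) and Penk (-0.49 ± 0.08) fell, the only 2 of 13 striatal genes that did, by either adjustment (2 adjusted over the list alone), with a camera adjusted p of 0.0178 and adjusted p = 0.338 with an estimated correlation. Among 16 ERK feedback genes Etv4 and Spred3 (-0.40 ± 0.07, named after its value was seen) fell (3 higher and 3 lower adjusted over the list alone), with a median of 0.01 and a mean of -0.10, and the list did not pass camera (adjusted p = 0.53). Spred3 did not pass in any of the 4 fits that leave out 1 library, with the Xist or HOX covariate, or without the 2 libraries with high Xist. Mki67 (0.10 ± 0.10), Tbr1 (-0.21 ± 0.11), Gad1 (-0.02 ± 0.07) and Rbfox3 (0.04 ± 0.07) did not pass.

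Another 4 lists passed camera, and edgeR, DESeq2 and the test adjusted over the list alone called 0 genes in each of them. Meningeal genes had a median of -0.19, with Ptgds, a prostaglandin synthase gene, at -0.48 ± 0.15 and 3 of 14 lower at an unadjusted p under 0.05. Erythroid genes had a median of -0.30, with Hba-a2 at -0.52 ± 0.20 and 1 of 7 lower at that threshold, and cholesterol synthesis genes -0.12, with Cyp51 at -0.21 ± 0.07 and 5 of 16 lower. Ependymal genes had a median of 0.23, with Dnah5, an axonemal dynein gene, at 0.34 ± 0.13 and 2 of 12 higher. Camera gave these lists, in that order, 0.000545, 0.0067, 0.0067 and 0.0178, and adjusted p = 0.48, 0.338, 0.541 and 0.419 with an estimated correlation.

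Of 11 HOX genes 6 fell, and 11 fell adjusted over the list alone, with a median of -3.44, a camera adjusted p of 2.83e-15 and adjusted p = 0.242 with an estimated correlation. Lbx1 and Lamp5 both fell by 1.83 on the log2 scale. Atoh1, which marks the rhombic lip, fell by 1.29, the 1 call among 16 cerebellar genes (3 adjusted over the list alone). Camera's adjusted p for the cerebellar list was 9.67e-05, and adjusted p = 0.201 with an estimated correlation. The mean log2 CPM of the HOX genes differed from the control mean by -3.03 and -4.13 in KO 1 and KO 2, so the glial and hindbrain groups moved in the same libraries. With that mean as a covariate, added after the data were seen, 103 genes passed, 36 of them shared with the 137, and 13 of the 40 named calls. Olig1, Olig2, Sox10, Pdgfra, Gfap, Fgfr3 and Egfr then still passed, with larger folds than without it. Sox10 went from 1.02 ± 0.16 to 1.65 ± 0.22 and Fgfr3 from 0.78 ± 0.10 to 1.17 ± 0.11. Vim (0.49 ± 0.12, adjusted p = 0.0836) and Nes (0.31 ± 0.12, adjusted p = 0.229) did not pass, nor did Nefh (-0.33 ± 0.14), Penk (-0.32 ± 0.15), Hoxb2 (-0.86 ± 0.49), Lbx1 (-0.62 ± 0.55) or Lamp5 (-0.45 ± 0.28). The loss of Hoxb2 and the other named HOX genes was largely fixed in advance, because the covariate is the mean of the HOX genes themselves. They count among the 27 calls lost. Of the 27 calls lost, 14 kept at least 75% of their log2 fold change, among them Sox8 (0.54 ± 0.15), Aldh1l1 (0.66 ± 0.15), Slc1a3 (0.46 ± 0.12), Eomes (-1.08 ± 0.25), Tac1 (-0.56 ± 0.16), Prr5l (1.19 ± 0.23) and Atoh1 (-1.20 ± 0.42). The median standard error of the 27 went from 0.16 to 0.277.

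Further named genes that rose were Col5a3, a fibrillar collagen gene (1.74 ± 0.22), Gna14 (1.56 ± 0.25), Prokr1 (1.46 ± 0.14), Inka2 (1.29 ± 0.12), Dio2, a deiodinase gene (1.18 ± 0.16), and Prr5l (2.18-fold). Leaving out 1 library left 26 genes (without control 1), 36 (without control 2), 23 (without KO 1) or 43 (without KO 2). Without the 2 libraries with high Xist 36 genes passed, with 16 of the 40 named calls and without Sox10, Pdgfra, Nes, Egfr and Slc1a3. With the Xist covariate 25 of the 40 passed, again without Sox10 and Slc1a3. Of the 40 named calls, 10 passed in all 4 of those fits, namely Etv1, Etv4, Etv5, Olig1, Olig2, Vim, Trib1, Inka2, Prokr1 and Prr5l, and 20 passed in none of them, among them the named HOX genes, Atoh1, Lbx1, Lamp5, Slc1a3, Pdpn, Eomes, Neurod1, Nefh, Tac1, Penk and Gna14. Gfap, Sox10, Sox8, Aldh1l1 and Col5a3 passed only without KO 2, Nes only without KO 1, Dio2 only without control 1, Pdgfra and Fgfr3 only without control 2 or KO 2, and Egfr only without control 2 or KO 1.

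**Figure D2:**
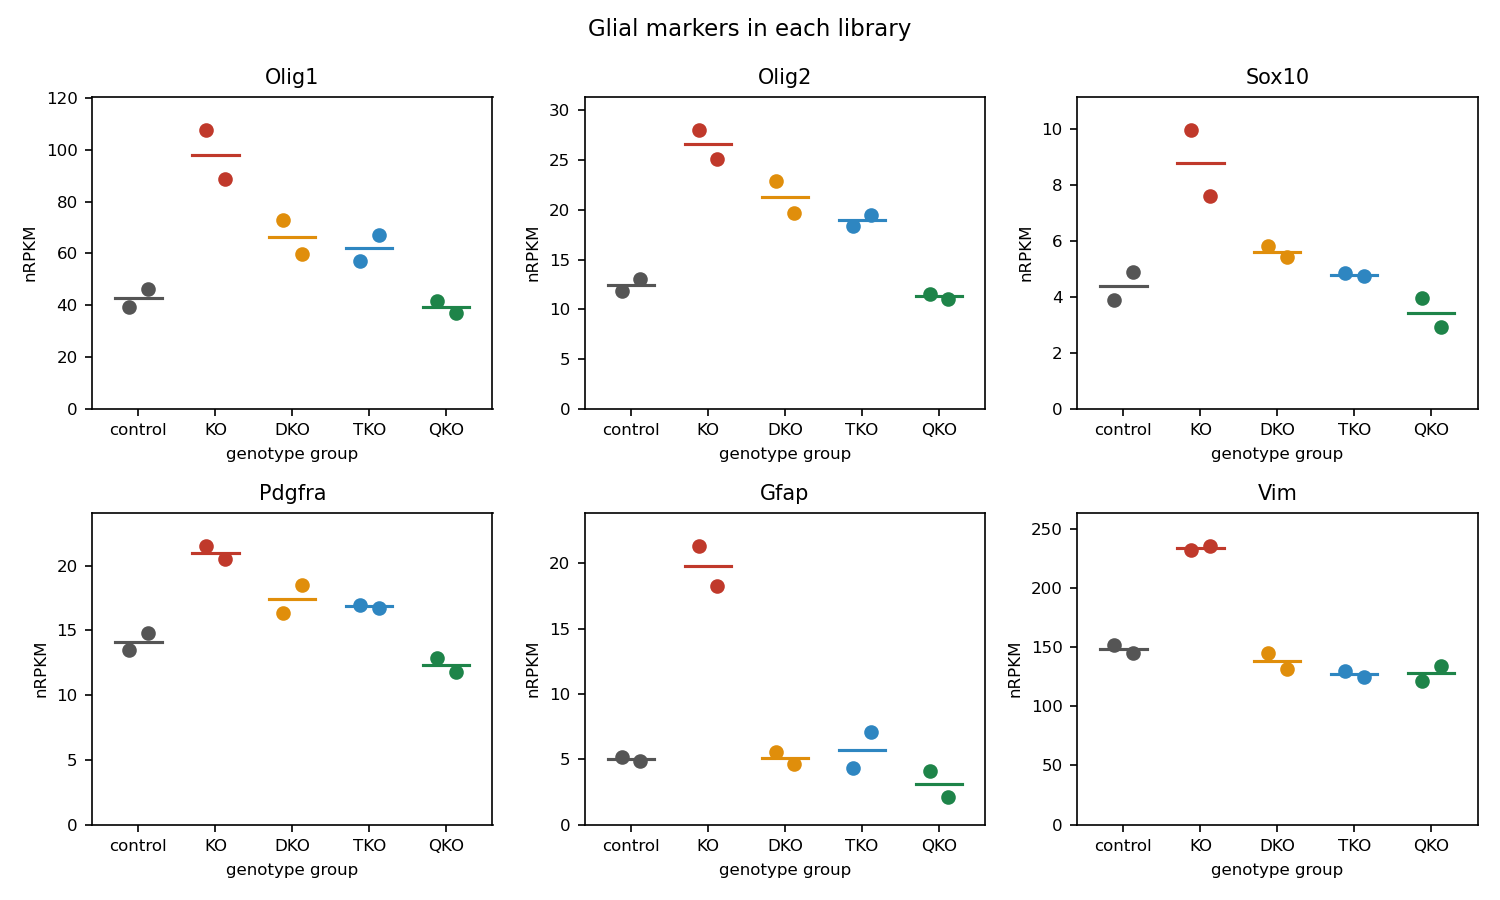
Normalised expression (nRPKM, linear axis from 0) of 4 oligodendrocyte lineage markers (Olig1, Olig2, Sox10, Pdgfra), Gfap and Vim in the 10 libraries, by genotype. Points are libraries and lines are means of 2; Olig2 lies at 28.0 and 25.1 in KO, between 18.4 and 22.9 in DKO and TKO, and between 10.998 and 13.0 in control and QKO, whereas Gfap and Vim in DKO are near the controls.

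DKO vs KO asked what the loss of cJun changes in brains without COP1. Filament genes and other genes of radial glia fell, 6 of the 19 on the radial glia list. Gfap fell 3.89-fold (-1.96 ± 0.26, n = 2 per group, edgeR adjusted p = 0.00546), Nes 2.03-fold (-1.02 ± 0.08) and Vim 1.70-fold (-0.77 ± 0.07). Egfr (-0.85 ± 0.09) and Tnc (-0.78 ± 0.12), an extracellular matrix gene, fell as well. Haemoglobin transcripts rose, Hba-a1 2.54-fold (1.35 ± 0.13), and Jun fell by 2.77 on the log2 scale. Cop1 (-0.09 ± 0.09), Etv1 (0.01 ± 0.12), Etv5 (0.24 ± 0.08) and Etv4 (0.50 ± 0.13) did not pass.

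In all, 106 genes changed, 37 higher and 69 lower. Of 19 radial glia genes 6 fell (9 adjusted over the list alone; camera adjusted p = 7.58e-07, and adjusted p = 0.0524 with an estimated correlation). Of 13 reactive glia genes 4 fell, and 5 fell and 1 rose adjusted over the list alone, with a camera adjusted p of 0.00109 and adjusted p = 0.206 with an estimated correlation. The OPC list had a median of -0.33. edgeR called 0 of its 15 genes, while 10 were lower and 1 higher adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 called 5 lower. Camera's adjusted p for it was 3.16e-06, and adjusted p = 0.232 with an estimated correlation. Olig2 (-0.33 ± 0.09, adjusted p = 0.173), Olig1 (-0.57 ± 0.13), Sox10 (-0.66 ± 0.16) and Pdgfra (-0.28 ± 0.08) did not pass. Cdon fell (-0.51 ± 0.09), the 1 call among 8 sonic hedgehog genes (2 adjusted over the list alone), and camera gave 0.0142, with adjusted p = 0.315 with an estimated correlation. Among 16 ERK feedback genes Spry4 rose (0.47 ± 0.08) and Ccnd1 fell (-0.47 ± 0.08), with 5 higher and 1 lower adjusted over the list alone. The ERK list had a camera adjusted p of 0.0451, and adjusted p = 0.255 with an estimated correlation. The 23 proliferation genes had a median of -0.18 and Mki67 was at -0.47 ± 0.10 (adjusted p = 0.0821). edgeR called 0 of them, against 1 lower adjusted over the list alone and by DESeq2 and 7 at an unadjusted p under 0.05. Camera gave that list 0.000646, and adjusted p = 0.528 with an estimated correlation. Cholesterol synthesis genes had a median of 0.12, with Cyp51 at 0.32 ± 0.07. edgeR called 0 of 16, against 1 higher adjusted over the list alone and by DESeq2 and 3 at an unadjusted p under 0.05, with a camera adjusted p of 0.00364 and adjusted p = 0.578 with an estimated correlation.

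Of 7 erythroid genes 5 rose (7 adjusted over the list alone), including Hba-a2 (1.74 ± 0.20) and the joint record of Hbb-b1 and Hbb-b2 (1.38 ± 0.15). That joint record counts as 2 of the 5 and as 2 of the 7. Globin genes have near-identical copies and may share reads with them, so their separate values are uncertain. The list had a camera adjusted p of 9.21e-15, and adjusted p = 0.0524 with an estimated correlation. Mean erythroid log2 CPM stood 1.05 above the control mean in both DKO libraries, beside the fall of the glial genes. Other named calls were Rps7 (1.27 ± 0.10), Mcmdc2 (3.32 ± 0.54), Gstm6 (1.47 ± 0.26), Car3 (1.27 ± 0.23) and Tmem267 (1.22 ± 0.23), all higher. Akr1c19 (-3.91 ± 0.39), H2-T24 (-3.11 ± 0.47), Casq1 (-1.46 ± 0.24), Nsun7 (-1.34 ± 0.25), Prokr1 (-1.29 ± 0.14), Galr2 (-1.12 ± 0.21), Col27a1 (-1.07 ± 0.18) and Cep250 (-1.06 ± 0.16) were lower. Leaving out KO 1, KO 2 or DKO 1 left 49, 42 and 58 genes, and a fit without the 2 libraries with high Xist left 62 (31 higher and 31 lower). Of the 27 named calls 12 passed in all 4 fits that leave out 1 library, among them Vim, Nes, Egfr, Jun, Hba-a1, Rps7, Prokr1 and Akr1c19, and Gfap passed in all but the fit without KO 1. Tnc was lost without KO 2 and without DKO 1, H2-T24 without KO 1 and without KO 2, Cdon and Ccnd1 in 3 of the fits, and Spry4, Car3, Tmem267, Col27a1, Galr2 and Nsun7 in all 4. DESeq2 called 22 of the 27, not Akr1c19, Casq1, Galr2, Gstm6 or Mcmdc2, and 18 passed with the Xist covariate and 17 without the libraries with high Xist, both without Tnc, Cdon and Spry4.

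TKO vs DKO asked what the label's further loss of ETV1 changes. Few genes passed. Some blood transcripts fell in the libraries labelled TKO, with Hba-a1 at -1.10 ± 0.13 (n = 2 per group, edgeR adjusted p = 0.00633) and the joint record of Hbb-b1 and Hbb-b2 at -1.04 ± 0.15. The high level was that of DKO: mean erythroid log2 CPM stood 1.05 above the control mean in both DKO libraries, and 0.15 and 0.07 above it in TKO. In TKO vs control edgeR called 0 erythroid genes. Rps7, a ribosomal protein gene (-1.07 ± 0.10), and Acp1, a phosphatase gene (-1.16 ± 0.13), also fell. Both lie on the chromosome of the targeted Etv1, 49 and 38 tested genes from it. Rps7 had been higher in DKO than in controls (1.43 ± 0.10). Etv1 itself rose 1.84-fold (0.88 ± 0.12), and H2-T24, a class I histocompatibility gene, rose by 3.43 ± 0.47. Olig2 (-0.16 ± 0.09), Olig1 (-0.09 ± 0.13), Sox10 (-0.23 ± 0.16), Gfap (0.16 ± 0.26) and Vim (-0.11 ± 0.07) did not pass, and neither did Cop1 (0.19 ± 0.09), Jun (-0.58 ± 0.23), Etv5 (0.28 ± 0.08) or Etv4 (0.37 ± 0.13).

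In all, 17 genes changed, 4 higher and 13 lower (31 and 52 by DESeq2, and 85 and 74 without the low-count filter). The other genes that rose were Rtraf (0.78 ± 0.10) and 2610507I01Rik (0.94 ± 0.09), a clone name given here after its value was seen. Rtraf-ps, a pseudogene named after its value was seen, fell (-1.47 ± 0.15), and it may share reads with Rtraf, so that their separate values are uncertain. H2-Q10 (-2.34 ± 0.34) and Tmem267 (-1.90 ± 0.25) fell. Of 7 erythroid genes 3 fell (5 adjusted over the list alone, with a camera adjusted p of 3.37e-11 and adjusted p = 0.142 with an estimated correlation). The 3 are Hba-a1 and the joint record of Hbb-b1 and Hbb-b2, which counts as 2. Interferon response genes had a median of 0.60. edgeR called 0 of 13, against 9 higher and 1 lower adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 also called 0. Irf7, a regulator of interferon genes, was at 1.25 ± 0.25 (adjusted p = 0.124) and Isg15 at 1.02 ± 0.21. Camera gave that list 1.89e-06, and adjusted p = 0.586 with an estimated correlation. HOX genes had a median of 1.66 and 4 of 11 higher adjusted over the list alone, with 0 called by edgeR or DESeq2, 7 at an unadjusted p under 0.05, a camera adjusted p of 4.47e-05 and adjusted p = 0.641 with an estimated correlation. Of 17 hypoxia genes, edgeR and DESeq2 called 0 and 9 were lower at an unadjusted p under 0.05. Adjusted over the list alone 4 were lower, with Ndrg1 at -0.24 ± 0.05. Camera gave the list 2.95e-06, and adjusted p = 0.586 with an estimated correlation. Meningeal genes had a median of 0.13, with Ogn at 0.43 ± 0.15, 0 of 14 called by edgeR or DESeq2 or adjusted over the list alone, and 2 higher at an unadjusted p under 0.05. Cholesterol synthesis genes had a median of -0.091, with Cyp51 at -0.28 ± 0.07. Of these 16 genes edgeR called 0, against 1 lower adjusted over the list alone and by DESeq2 and 2 at an unadjusted p under 0.05. Both lists passed camera, at 0.0387 and 0.0125, with adjusted p = 0.678 with an estimated correlation for both. Without TKO 1 the count was 2 (1 higher and 1 lower), without TKO 2 it was 9 and without DKO 1 it was 43, and 60 genes passed without the 2 libraries with high Xist. Of the 11 named calls, 0 passed in all 4 edgeR fits that leave out 1 library, and DESeq2 called 11 with all libraries. Rps7 and Acp1 passed in all but the fit without TKO 1, while Etv1 and Rtraf passed only without DKO 2 and were lost without the libraries with high Xist. Rtraf-ps and 2610507I01Rik were lost without TKO 1. With the HOX covariate 4 of the 11 passed, Hba-a1, Rps7, Acp1 and Rtraf, and the 7 lost, Etv1 (0.87 ± 0.14) among them, kept at least 75% of their log2 fold change.

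QKO vs TKO asked what the label's further loss of ETV5 changes. In the libraries labelled QKO 3 OPC genes and 1 astrocyte gene fell. Olig2 was 1.69-fold lower (-0.76 ± 0.09, n = 2 per group, edgeR adjusted p = 0.00346), Pdgfra 1.37-fold (-0.46 ± 0.08), Sox8 1.38-fold (-0.46 ± 0.08) and Aqp4, the astrocyte water channel, 1.78-fold (-0.83 ± 0.15). Serpina3n, a protease inhibitor gene of reactive astrocytes, rose 2.92-fold (1.55 ± 0.16). Egr1, an immediate early gene, rose by 0.88 ± 0.12 and Etv4 by 0.81 ± 0.12, while Etv5 (0.07 ± 0.08), Cop1 (-0.05 ± 0.09), Jun (0.17 ± 0.24) and Etv1 (0.27 ± 0.11) did not pass.

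In all, 54 genes changed, 22 higher and 32 lower. Of 15 OPC genes 3 fell (8 adjusted over the list alone; camera adjusted p = 7.9e-12, and adjusted p = 0.232 with an estimated correlation), while Olig1 (-0.66 ± 0.13, adjusted p = 0.0875) and Sox10 (-0.49 ± 0.17) did not pass. Of 18 astrocyte genes 1 fell (8 adjusted over the list alone), with Sparcl1 at -0.42 ± 0.08 (adjusted p = 0.0749), Slc1a3 at -0.32 ± 0.07 and Fgfr3 at -0.45 ± 0.10. Camera gave that list 3.13e-13, and adjusted p = 0.282 with an estimated correlation. Gfap (-0.89 ± 0.27) and Vim (-0.00 ± 0.07) did not pass. Interferon response genes had a median of -0.90. edgeR called 0 of 13, against 10 lower adjusted over the list alone, 11 at an unadjusted p under 0.05 and 1 by DESeq2, with a camera adjusted p of 1.5e-14 and adjusted p = 0.232 with an estimated correlation. The intermediate progenitor list had a median of 0.20, with Neurog2 at 0.46 ± 0.15 and Eomes at 0.39 ± 0.15. edgeR and DESeq2 called 0 of its 12 genes, 4 were higher at an unadjusted p under 0.05 and 0 adjusted over the list alone, and camera gave 1.58e-06, with adjusted p = 0.282 with an estimated correlation. Erythroid genes had a median of 0.19, with the joint record of Hbb-b1 and Hbb-b2 at 0.33 ± 0.15. edgeR and DESeq2 called 0 of these 7, with 0 adjusted over the list alone and 2 higher at an unadjusted p under 0.05, and camera gave 0.0228, with adjusted p = 0.674 with an estimated correlation.

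Other named genes that changed lay outside these lists. Akr1c19 (3.68 ± 0.29), Tmem267 (1.99 ± 0.25), Pla2g4e (1.57 ± 0.17), Eif3j2 (1.53 ± 0.25), Ero1b (1.52 ± 0.13), Scg5 (0.80 ± 0.11) and Alad (0.74 ± 0.12) rose. Rec8, a meiotic cohesin gene (-2.68 ± 0.29), Car3 (-1.63 ± 0.25), Crb1 (-1.56 ± 0.14), Gstm6 (-1.46 ± 0.24), Ublcp1 (-1.34 ± 0.22), Metap1d (-1.28 ± 0.13), Gpr137b (-1.17 ± 0.09), Lyrm7 (-1.12 ± 0.13), Ubb (-1.12 ± 0.16) and Irgm1 (-1.06 ± 0.16) fell. Eif3j2, Ubb and Gpr137b have near-identical copies that may take some of their reads. The count was 26 without TKO 1, 24 without TKO 2 (14 higher and 10 lower), 83 without QKO 1 and 34 without QKO 2. Of the 24 named calls 8 passed in all 4 of those fits, Serpina3n, Akr1c19, Crb1, Ero1b, Gpr137b, Lyrm7, Metap1d and Rec8, whereas Olig2 was lost without TKO 2, Pdgfra, Aqp4 and Etv4 passed only without QKO 1, Egr1 was lost without TKO 1 and without TKO 2, and Sox8, Gstm6 and Ublcp1 passed in none. Aqp4 and Sox8 were also lost with the Xist covariate and without the libraries with high Xist. All TKO and QKO libraries have the male pattern, so these losses cannot come from a sex imbalance between the groups.

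QKO vs control asked how far the libraries labelled as lacking all 4 factors differ from controls. Glial markers that were higher in KO did not pass here: Olig2 was at -0.14 ± 0.09 (n = 2 per group, edgeR adjusted p = 0.831), Olig1 at -0.11 ± 0.13, Sox10 at -0.36 ± 0.17, Gfap at -0.70 ± 0.27 and Vim at -0.22 ± 0.07. Serpina3n rose 3.10-fold (1.63 ± 0.16) and Spp1, a secreted phosphoprotein gene, 2.05-fold (1.04 ± 0.17). Jun fell 8.60-fold (-3.10 ± 0.22) and Etv5 1.73-fold (-0.79 ± 0.08), while Etv4 (-0.54 ± 0.11), Etv1 (-0.11 ± 0.11) and Cop1 (-0.22 ± 0.09) did not pass. Ednrb, an endothelin receptor gene expressed in radial glia, fell 1.56-fold (-0.64 ± 0.07).

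In all, 44 genes changed, 25 higher and 19 lower. That balance turned with DESeq2 (41 and 50), without the low-count filter (60 and 62) and with the Xist covariate (12 and 21). It also turned without the 2 libraries with high Xist. Of 19 radial glia genes Ednrb alone fell, by either adjustment (1 adjusted over the list alone), and the list had a median of -0.16, a camera adjusted p of 9.12e-06 and adjusted p = 0.158 with an estimated correlation. The astrocyte list had a median of -0.17. edgeR called 0 of 18, against 2 lower adjusted over the list alone and by DESeq2 and 6 at an unadjusted p under 0.05, and Sparcl1 was at -0.45 ± 0.08 (adjusted p = 0.057). Camera gave it 7.04e-07, and adjusted p = 0.334 with an estimated correlation. The OPC list had a median of -0.15, with 0 of 15 called by edgeR or DESeq2 or adjusted over the list alone, 2 lower at an unadjusted p under 0.05, a camera adjusted p of 0.000772 and adjusted p = 0.334 with an estimated correlation. HOX genes had a median of -0.94, with 0 of 11 called by either tool or adjusted over the list alone, 3 lower at an unadjusted p under 0.05, a camera adjusted p of 4e-10 and adjusted p = 0.334 with an estimated correlation. Their mean differed from that of controls by -0.16 in QKO 1 and -3.01 in QKO 2.

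In the other lists that passed camera for QKO vs control, edgeR and DESeq2 called 0 genes, apart from 1 DESeq2 call among the interferon response genes. Lower medians were those of neuronal maturation (-0.12, 8 of 20 lower at an unadjusted p under 0.05), vascular (-0.13, 3 of 15), subplate and Cajal-Retzius (-0.093, 2 of 13), meningeal (-0.095, 1 of 14), cerebellar (-0.080, 1 of 16) and hypoxia genes (-0.064, 1 of 17). Higher medians were those of erythroid (0.36, 3 of 7 higher), choroid plexus (0.18, 3 of 12) and ependymal genes (0.14, 0 of 12). Adjusted over the list alone, 1 of the cerebellar genes was lower, Atoh1 (-0.92 ± 0.21), and 0 in each of the other 8. Camera gave these 9 lists between 0.000534 and 0.0364, and the lowest was adjusted p = 0.334 with an estimated correlation.

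Further named genes that changed lay outside these lists. H2-T24 (2.48 ± 0.40), Akr1c19 (1.58 ± 0.23), Pla2g4e (1.51 ± 0.17), Ero1b (1.38 ± 0.12), Dsp (1.10 ± 0.19), Rpa3 (0.88 ± 0.15), Scg5 (0.82 ± 0.11) and Prnd (0.77 ± 0.13) rose. Lyrm7 (-1.18 ± 0.13), Ubb (-1.09 ± 0.16), Gpr137b (-1.01 ± 0.09), Crb1 (-1.01 ± 0.14), Metap1d (-1.01 ± 0.13), Samd9l (-0.93 ± 0.15) and Mrpl55 (-0.72 ± 0.11) fell. The count was 17 without control 1 and without control 2, 49 without QKO 1 (17 higher and 32 lower), and 68 without QKO 2. Of the 20 named calls 6 passed in all 4 fits that leave out 1 library, Jun, Etv5, Serpina3n, Ero1b, Gpr137b and Lyrm7, while Ednrb was lost without control 1, Spp1, H2-T24 and Crb1 passed only without QKO 2, and Dsp, Prnd and Samd9l passed in none. With the Xist covariate 12 of the 20 passed and without the libraries with high Xist 9, both without Spp1, Akr1c19 and Crb1, and 16 passed with the HOX covariate, where the 4 lost kept at least 75% of their log2 fold change.

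DKO vs control left Olig2 higher and Gfap near its control level. Olig2 was 1.71-fold higher in DKO (0.78 ± 0.09, n = 2 per group, edgeR adjusted p = 0.00249), and Olig1 (0.64 ± 0.13, adjusted p = 0.0791), Gfap (0.03 ± 0.26) and Vim (-0.10 ± 0.07) did not pass. Etv4 (-1.72 ± 0.12), Etv1 (-1.26 ± 0.11) and Etv5 (-1.14 ± 0.08) fell as in KO. Jun (-2.69 ± 0.21), which did not pass in KO vs control, fell here, while Cop1 (-0.37 ± 0.09) did not pass. In all, 79 genes changed, 56 higher and 23 lower. Of 15 OPC genes 1 rose (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00044, and adjusted p = 0.331 with an estimated correlation). Of 19 radial glia genes Hes1 rose (0.68 ± 0.11) and Nes (-0.45 ± 0.08) and Pdpn (-0.67 ± 0.09) fell, with 1 higher and 4 lower adjusted over the list alone, a camera adjusted p of 0.00079 and adjusted p = 0.21 with an estimated correlation. Spry1 (0.55 ± 0.08) and Dusp6 (0.43 ± 0.08), feedback inhibitors of ERK signalling, rose, and Spred3 fell (-0.48 ± 0.07). With Etv4, these made 2 higher and 2 lower of 16 ERK feedback genes (4 and 2 adjusted over the list alone), a list that did not pass camera (adjusted p = 0.221). Of 7 erythroid genes 5 rose, by either adjustment (5 adjusted over the list alone), Hba-a1 by 1.28 ± 0.13, with a camera adjusted p of 3.07e-15 and adjusted p = 0.0725 with an estimated correlation. The joint record of Hbb-b1 and Hbb-b2 (1.08 ± 0.15) counts as 2 of the 5. Another 13 lists passed camera, between 1.75e-14 (HOX) and 0.0286, none of them with an estimated correlation, where the lowest was adjusted p = 0.331. Their medians were -2.53 for HOX, -0.27 for subplate, -0.26 for interferon response, -0.19 for olfactory bulb, -0.17 for meningeal, -0.13 for cerebellar, -0.10 for differentiating oligodendrocyte, -0.089 for intermediate progenitor and -0.076 for proliferation genes. For pituitary and muscle genes the median was 0.54, for hypothalamic genes 0.27, for ependymal genes 0.25 and for hypoxia genes 0.096. Skor1 fell (-0.97 ± 0.18), the 1 call among 9 olfactory bulb genes (2 adjusted over the list alone). Mean HOX log2 CPM differed from the control mean by -3.12 and -2.35 in the DKO libraries. Car3 (2.51 ± 0.26), Gna14 (1.95 ± 0.24), Gcnt4 (1.59 ± 0.22), Rps7 (1.43 ± 0.10) and Kcnn4 (1.42 ± 0.20) rose, and Akr1c19 (-3.72 ± 0.40) and Aim2 (-1.29 ± 0.21) fell. The count was 27 without control 1, 30 without control 2 and 34 without the 2 libraries with high Xist. Of the 23 named calls 8 passed in all 4 fits that leave out 1 library, while Olig2 was lost without control 1, Pdpn without control 1 and without control 2, Spry1, Spred3 and Hes1 in 3 of the fits, and Dusp6, Nes and Aim2 in all 4. Olig2, Spry1, Dusp6, Spred3 and Hes1 were also lost without the high-Xist libraries, where 10 of the 23 passed, and with the HOX covariate, where 7 of the 23 passed and 32 genes in all. With that covariate 12 of the 16 lost calls kept at least 75% of their log2 fold change, among them Olig2 (0.85 ± 0.14, adjusted p = 0.0562) and Hba-a1 (1.19 ± 0.20, adjusted p = 0.0509), while Dusp6 stood at 0.27 ± 0.11.

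TKO vs control again left Olig2 higher, 1.53-fold (0.61 ± 0.09, n = 2 per group, edgeR adjusted p = 0.0208), and Jun (-3.27 ± 0.22), Etv4 (-1.35 ± 0.12) and Etv5 (-0.85 ± 0.08) lower. Cop1 (-0.18 ± 0.09), Etv1 (-0.38 ± 0.11), Olig1 (0.55 ± 0.13), Pdgfra (0.26 ± 0.08), Gfap (0.19 ± 0.26) and Vim (-0.21 ± 0.07) did not pass. In all, 28 genes changed, 20 higher and 8 lower. Of 15 OPC genes 1 rose (4 adjusted over the list alone; camera adjusted p = 0.00133, and adjusted p = 0.519 with an estimated correlation). Besides the interferon response genes, 8 other lists passed camera, between 0.000132 (HOX) and 0.0339, and the lowest was adjusted p = 0.353 with an estimated correlation. Their medians were -1.07 for HOX, -0.22 for intermediate progenitor, -0.14 for radial glia, -0.12 for cerebellar, -0.10 for hypoxia and for cholesterol synthesis, -0.089 for neuronal maturation and 0.28 for ependymal genes. Rec8 (3.44 ± 0.32), Car3 (2.27 ± 0.27), Gstm6 (1.73 ± 0.25), Hjurp, a centromere chaperone gene (1.00 ± 0.07), and Inka2 (0.99 ± 0.12) rose, and Akr1c19 (-2.11 ± 0.32) and Mcm6, a replication helicase gene (-0.47 ± 0.06), fell. The count was 18 without control 1, 13 without control 2, 15 without TKO 1 and 13 without TKO 2 (5 higher and 8 lower), and Olig2, Akr1c19, Gstm6 and Mcm6 passed in none of these fits. Without the libraries with high Xist Olig2, Akr1c19 and Gstm6 were lost as well.

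QKO vs KO showed several glial genes lower in the libraries labelled QKO. Gfap fell 6.45-fold (-2.69 ± 0.27, n = 2 per group, edgeR adjusted p = 0.000582), Sox10 2.60-fold (-1.38 ± 0.16), Olig1 2.51-fold (-1.33 ± 0.13), Olig2 2.37-fold (-1.25 ± 0.09) and Vim 1.84-fold (-0.88 ± 0.07). Eomes rose 1.68-fold (0.75 ± 0.15), as did Etv4 3.21-fold (1.68 ± 0.12), Etv1 2.24-fold (1.16 ± 0.11) and Etv5 1.51-fold (0.59 ± 0.08). Jun fell (-3.18 ± 0.22) and Cop1 did not pass (0.05 ± 0.09). In all, 240 genes changed, 66 higher and 174 lower. Of 15 OPC genes 7 fell (12 adjusted over the list alone; camera adjusted p = 1.87e-18, and adjusted p = 0.0606 with an estimated correlation). Of 18 astrocyte genes 6 fell, among them Fgfr3 (-1.01 ± 0.10), Aldh1l1 (-0.68 ± 0.08) and Slc1a3 (-0.56 ± 0.07), with 9 lower and 2 higher adjusted over the list alone, a camera adjusted p of 7.57e-09 and adjusted p = 0.321 with an estimated correlation. Of 19 radial glia genes 8 fell, including Ednrb (-0.79 ± 0.07), Egfr (-0.85 ± 0.09) and Nes (-0.76 ± 0.08), with 11 lower and 3 higher adjusted over the list alone, a camera adjusted p of 2.82e-08 and adjusted p = 0.0606 with an estimated correlation. Of 13 reactive glia genes 4 fell and Serpina3n rose (1.32 ± 0.15), with 4 lower and 2 higher adjusted over the list alone, a camera adjusted p of 0.0185 and adjusted p = 0.321 with an estimated correlation. HOX genes had a median of 2.74, with 11 of 11 higher adjusted over the list alone and at an unadjusted p under 0.05, 3 by DESeq2 and 0 by edgeR over all genes. Camera gave them 4.27e-06, and adjusted p = 0.53 with an estimated correlation. The HOX rise lay mainly in QKO 1. Mean HOX log2 CPM differed from the control mean by -0.16 in QKO 1 and -3.01 in QKO 2, against -3.03 in KO 1 and -4.13 in KO 2. The erythroid list had a median of 0.68, the intermediate progenitor list, with Eomes, 0.25, the striatal list, in which Tac1 rose (0.43 ± 0.09), 0.19, and the sonic hedgehog list, in which Cdon fell (-0.52 ± 0.09), -0.21. These 4 passed camera, between 3.58e-07 and 0.0185, and the lowest was adjusted p = 0.123 with an estimated correlation. Adjusted over the list alone, 6 erythroid, 3 intermediate progenitor and 4 striatal genes were higher and 1 sonic hedgehog gene lower. The count was 74 without KO 1, 85 without KO 2 and 135 without QKO 2, and of the 28 named calls 18 passed in all 4 fits that leave out 1 library, including Gfap, Olig1, Olig2, Sox10, Pdgfra, Vim, Nes and Fgfr3. Eomes passed only without QKO 1, Etv5 was lost without KO 1 and without KO 2, and Tac1 and Cdon passed in none of these fits, nor with the HOX covariate, where they stood at 0.45 ± 0.12 and -0.51 ± 0.12.

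**Figure D3:**
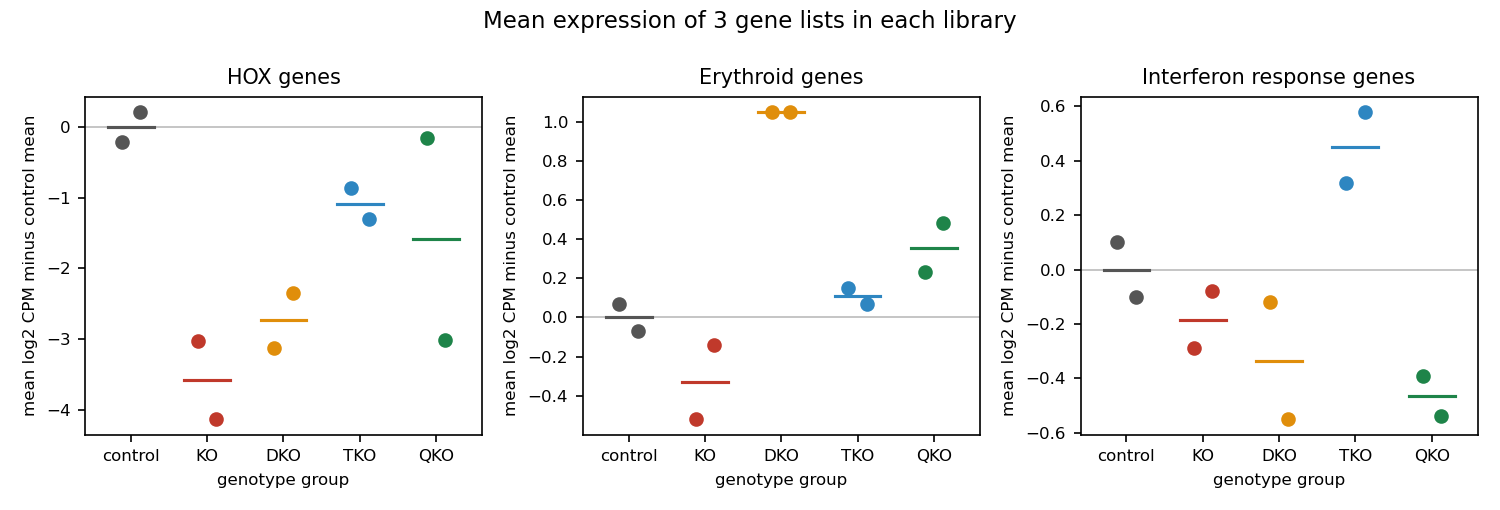
Mean log2 CPM of the tested HOX, erythroid and interferon response genes in the 10 libraries, as the difference from the control mean, by genotype. Points are libraries and lines are means of 2; the HOX mean is at -3.03 and -4.13 in KO and at -0.16 and -3.01 in QKO, and the erythroid mean is at 1.05 in both DKO libraries.

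Over the 500 genes that differed most between KO and control, DKO kept 31.3% of the KO change (range -7.2 to 60.7% over 4 splits and 2 libraries), TKO 65.1% (48.6 to 79.3%) and QKO 19.1% (-20.9 to 65.1%). The libraries of a group differed: the share was 52.9% without DKO 1 and 8.0% without DKO 2, and -6.7% without QKO 1 and 45.4% without QKO 2. Over the 61 genes of the OPC, astrocyte, reactive glia and radial glia lists, a choice added after the data were seen, DKO kept 31.9% (27.9 to 35.8%), TKO 21.4% (13.7 to 32.8%) and QKO -20.7% (-35.4 to -12.7%). No test was run on the differences between these shares.

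Of the KO calls, leaving aside the targeted genes, 135 were compared with those of the other genotypes. In the same direction against the controls, 22 were called in DKO, 9 in TKO and 8 in QKO, and 3, 2 and 0 in the opposite direction, among 76, 26 and 42 calls. Independent lists of these sizes would share 0.33, 0.11 and 0.16 genes. Simulated unchanged groups, set against shared simulated controls, shared a mean of 0.30, 0.35 and 0.25, with a highest value of 3, 2 and 2. Part of the excess may come from the shared controls, which were not split for this overlap. Part may come from differences between libraries that many genes share, which the simulations lack. The covariance of log2 fold changes with KO vs control was 0.0577 for DKO, 0.0683 for TKO and 0.0611 for QKO, against simulated values of 0.0303, 0.0303 and 0.0302, so the differences were 0.0274, 0.0380 and 0.0309. Measured against KO, 32 of the 135 KO calls turned back toward the control level in DKO, 31 in TKO and 84 in QKO. These comparisons had 105, 59 and 237 calls, so the counts turned back do not rank the genotypes. TKO vs KO, outside the 8 comparisons, was fitted for this count only. The 84 comprised 71 of the genes higher in KO and 13 of those lower in KO. Simulated groups equal to KO turned back a mean of 0.25, 0.15 and 0.50 genes, with a highest value of 4, 1 and 2, and independent lists 0.42, 0.25 and 1.01. The KO libraries are shared here, and part of this excess may come from them or from such differences between libraries.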

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

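The fits without the 2 libraries with high Xist, those with the HOX covariate and the share over glial genes were chosen after the data were seen. Counts of genes changed with RLE size factors and with a minimum of 1 CPM stayed within 1.5 times the reported counts in all 8 comparisons. No paired analysis was possible because the labels number no replicates across genotypes. Precision is limited by 2 libraries per group and by library totals between 31996944 and 54594523 counts.

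DESeq2 called 243 genes for KO vs control, 223 for DKO vs KO, 83 for TKO vs DKO, 100 for QKO vs TKO, 91 for QKO vs control, 141 for DKO vs control and 88 for TKO vs control. Without the low-count filter, which tested 24830 genes, edgeR called 300, 336, 159, 160, 122, 225 and 145 genes in the same order, and 487 for QKO vs KO. A fit of the 2 groups alone called 671 for KO vs control, 63 for DKO vs KO, 60 for TKO vs DKO, 23 for QKO vs control and 521 for TKO vs control. The Xist covariate gave 60 for KO vs control, 64 for DKO vs KO and 46 for TKO vs DKO. Without the 2 libraries with high Xist the counts were 36, 62 and 60 in that order, and 34 for DKO vs control. The HOX covariate gave 414 for DKO vs KO, 32 for DKO vs control and 118 for TKO vs control. For these counts the cause was not tested.

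Leaving out 1 library at a time gave between 23 and 43 genes for KO vs control, 42 and 122 for DKO vs KO, 2 and 43 for TKO vs DKO, 24 and 83 for QKO vs TKO, 17 and 68 for QKO vs control, 27 and 69 for DKO vs control, 13 and 18 for TKO vs control, and 74 and 267 for QKO vs KO. Where fewer libraries lowered the count, fewer replicates are part of the alternative itself.

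Lists called by camera with its preset correlation numbered 14, 9, 6, 5 and 14 in the main comparisons, in the order above, and 16, 10 and 9 in the others. An estimated correlation gave 0 in all 8, with 6, 6, 2, 4, 3, 5, 1 and 5 at an unadjusted p under 0.05. fry called 4 lists for KO vs control, 4 for DKO vs KO, 1 for TKO vs DKO, 1 for DKO vs control and 3 for QKO vs KO, and 0 for QKO vs TKO, QKO vs control and TKO vs control. Leaving out 1 library gave between 11 and 19 lists for KO vs control, 8 and 12 for DKO vs KO, 4 and 10 for TKO vs DKO, 5 and 12 for QKO vs TKO, 5 and 17 for QKO vs control, 8 and 15 for DKO vs control, 8 and 15 for TKO vs control, and 8 and 12 for QKO vs KO.

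With a mean log2 CPM of at least 0 and of at least 4, the share of the KO change kept was 39.5 and 19.7% in DKO, 50.8 and 54.7% in TKO, and 31.0 and 11.6% in QKO. Over the glial lists it was 21.4% in TKO and -20.7% in QKO. The cause of these moves was not tested. Without 1 library the shares lay between 8.0 and 52.9% for DKO, 62.8 and 66.8% for TKO, and -6.7 and 45.4% for QKO.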

Other observations

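The test of microglial and vascular genes, those of neighbouring calls and the test of the chromosomes of called genes were chosen after the result was seen, and the other tests before, though the HOX covariate was itself added after the data were seen. Genes of differentiating oligodendrocytes had a median log2 fold change of -0.15 in KO vs control, against 0.40 for OPC genes. Among members named after their values were seen, Mbp, which encodes myelin basic protein, stood at -0.07 ± 0.07 (n = 2 per group), Mog, a myelin glycoprotein gene, at 0.17 ± 0.14 and Cldn11, a claudin gene, at -0.43 ± 0.16, whereas Olig1 rose by 1.21 ± 0.13. edgeR called 0 of these 10 genes, by either adjustment (0 adjusted over the list alone), as did DESeq2, and 1 was lower at an unadjusted p under 0.05. The list did not pass camera (adjusted p = 0.14, and adjusted p = 0.53 with an estimated correlation). The 13 interferon response genes had a median of 0.42 in TKO vs control and -0.48 in QKO vs control, with Usp18 at 1.10 ± 0.28 in the former. In TKO vs control, edgeR and DESeq2 called 0, 5 were higher at an unadjusted p under 0.05 and 1 adjusted over the list alone, and camera gave 0.000802, with adjusted p = 0.519 with an estimated correlation. In QKO vs control, edgeR called 0, DESeq2 1, 6 were lower at an unadjusted p under 0.05 and 1 adjusted over the list alone, and camera gave 2.02e-05, with adjusted p = 0.334 with an estimated correlation. Mean interferon log2 CPM lay 0.32 and 0.58 above the control mean in TKO and at -0.39 and -0.54 in QKO.

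Pituitary hormone transcripts were high in 1 library of DKO and 1 of QKO. Gh, the growth hormone gene, had 7730 counts (187 nRPKM) in DKO 1, 1884 (55.6 nRPKM) in QKO 1 and 68 in KO 1, and between 0 and 3 counts in the other 7 libraries. Pomc stood at 26.4 nRPKM in DKO 1, at 3.11 in QKO 1 and between 0.624 and 1.23 in the others. The list of 11 pituitary and muscle genes passed camera in DKO vs KO (adjusted p = 0.0147, and adjusted p = 0.232 with an estimated correlation), where edgeR and DESeq2 called 0 of them, 5 were higher at an unadjusted p under 0.05 and 4 adjusted over the list alone.

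The rise of OPC genes in KO was set against a smaller share of neurons and against less caudal hindbrain. A smaller share of neurons would raise other cell types alike, but 29 microglial and vascular genes had a median log2 fold change of -0.071 (quartiles -0.116 to 0.023) against 0.396 for the 15 OPC genes (quartiles 0.194 to 0.752). With the HOX mean as a covariate the OPC median was 0.732, with 6 genes called, and the median standard error went from 0.135 to 0.219. The microglial and vascular median argues against a smaller share of neurons as the whole cause of the OPC rise. The covariate cannot decide on less hindbrain. Its slope comes from HOX differences between libraries of 1 genotype, the widest being QKO 1 and QKO 2 (-0.16 and -3.01 from the control mean). That slope was carried over to KO (-3.03 and -4.13), whose HOX means lie apart from those of the controls (-0.21 and 0.21). A change in the number or state of OPCs after the loss of COP1 stays open and was not tested.

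The fall of HOX genes in KO was set against a loss of weakly expressed genes and against less caudal hindbrain in the samples. Genes matched to the HOX genes on mean expression, 507 in all, had a median of 0.045 (quartiles -0.168 to 0.301) against -3.44 for HOX genes, which argues against a loss of weak genes as a class. Hindbrain markers other than HOX genes had a median of -0.545 (quartiles -1.08 to -0.318), with 12 of 12 lower and a smallest edgeR adjusted p of 0.105. Slc6a5, a glycine transporter gene, stood at -2.41 ± 0.58. This is consistent with less hindbrain tissue in the KO libraries, which the level of dissection could set. A change of hindbrain development in KO stays open and was not tested.

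Genes such as Akr1c19, Rec8 and Gpr137b changed strongly between genotypes with no shared function, as genes that differ between mouse strains can, and of 46 called genes in QKO vs TKO with a known place, HOX, erythroid and targeted genes left aside, 8 pairs lay within 10 tested genes of each other, against a highest value of 7 in 10000 random sets (one-sided permutation p = 1e-04, the smallest they can give). Against 1000 random sets, KO vs control had 16 pairs (highest random value 18, permutation p = 0.006), TKO vs DKO had 0 among the 11 calls counted that way (p = 1), and the other 5 comparisons gave p between 0.001, the smallest these can give, and 0.031. The 8 pairs are consistent with strain haplotypes that differ between the crosses, though neighbours that share regulation or reads could also pair: Ero1b, Gpr137b and Gpr137b-ps made 3 of them, Akr1c19 and Marcksl1-ps4 another, and 5 pairs were left without pseudogenes (permutation p = 0.0041). Pseudogenes made up 10.87% of the 46 named calls and 2.05% of tested genes (Fisher's exact p = 0.00244, two-sided), so reads shared between copies may add to the pattern. DNA flanking the targeted alleles is argued against for 36 of the 46 calls, which lie on chromosomes that hold no targeted gene. Over the 4 loci, each in its own comparison, it cannot be told apart from chance. Of 80 neighbouring genes 1, Tusc1 near Jun, was called (1.25% against 0.407% elsewhere, Fisher's exact p = 0.279). On the chromosome of Jun, 5 of 1065 genes were called in DKO vs KO, Tnc and Col27a1 among them, against 89 of 16019 elsewhere. On that of Etv5, 1 of 518 genes was called in QKO vs TKO, Olig2, against 45 of 16566 elsewhere. On the whole chromosome of Etv1 2 of 631 genes were called in TKO vs DKO, Rps7 and Acp1, against 12 of 16453 elsewhere (Fisher's exact p = 0.0925). Rps7 had already risen in DKO vs KO (1.27 ± 0.10), before the label's loss of ETV1.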
